A study of Arabidopsis thaliana with 4 samples.

How the data were processed

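The data were 4 single-channel Affymetrix arrays of Arabidopsis thaliana, 1 for each combination of genotype (Col-0 wild type or erf6-1) and light (untreated, or 2 h at 2000 µmol m-2 s-1). Groups were taken from the sample titles. A description field in all 4 records refers to early embryos, which is at odds with the plant material, and was not used. According to the labels, the authors scaled each array with MAS5, whose version is not given in the sources used here, and the deposited values are linear signals in intensity units. The values bear this out in that the 2% trimmed means were nearly equal. The medians ranged from 207 to 321, so the arrays had been neither quantile normalised nor set to equal medians. The table had no missing values. Raw files and detection calls were not used here.

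Probe sets were joined to genes with the supplied table of probe sets and Entrez genes and named by the supplied RefSeq gene table. Of 22746 probe sets, 14016 were listed, 13513 with 1 gene, of which 13436 matched a current locus. Only these were named, and they cover 13286 genes. The 503 probe sets with several genes and the 8730 not listed were kept in counts without a name. ERF6 was not analysed here, so the planned check of the labels against the signal of the mutated gene was not made. Affymetrix control probe sets were not used here, so the planned measure of error from spike-in controls was not made either.

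Before the data were examined, the following settings were fixed. Values were used as deposited, raised to a floor at the 30th percentile of all values pooled (100.0), and put on the log2 scale. A probe set entered the counts if its highest array reached the pooled median of 248.6, which 17173 did (75.5%), 9710 of them named. Differences between 2 arrays were called at 2-fold. Probe sets were called bright when their mean log2 signal reached the pooled 75th percentile of 588, which held for 4964. Where the lower of 2 arrays was under the floor, the fold is a bound and written as at least. Where both were, no fold is given for the gene. The plan gave such a probe set no value, but in the calculation it entered medians, percentiles and correlations with a difference of 0. With 1 array per group there is no p-value or standard error for a difference between 2 groups or between the responses, and the number of arrays limits the precision. An additive fit of genotype and light would leave 1 residual degree of freedom, but would take any difference between the responses for error, and was not made.

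Named genes followed a rule fixed at the same time. It took, for each of the 4 pairs of arrays, the 12 highest and 12 lowest log2 differences among named probe sets above the floor on both arrays, and the 5 largest bounds each way. For the difference between responses it took the 12 highest and 12 lowest above the floor on all 4 arrays. From each gene list it took, in each comparison, up to 4 measured members with the largest difference, and a gene named in 1 comparison could be followed in the others. Genes and families outside that rule were chosen after their values were seen and are said to be so; for single plastid genes this holds for rpoA, psbD and rps14 without treatment.

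The 24 gene lists were fixed in advance, each compared through the median log2 difference of its measured members and the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins. Percentiles below 2.5 or above 97.5 are described as apart from random lists. They describe these arrays and are not tests between genotypes or treatments. Only 71 of the 412 listed genes had a named probe set. Of these, 66 passed the filter and are called measured. Genes without a named probe set were not identified here, which does not mean that the array lacks them. So 6 lists had the 5 members needed for a percentile, 13 had 1 to 4 and 5 had none. A further 16 families, plastid-encoded genes among them, were formed from gene symbols or chromosome after values of single genes had been seen. Over all of these, 110 percentiles were computed and 24 lay outside the limits. Had the lists been independent and chosen without sight of the values, 5.5 would be outside. That number is no chance rate here: the families were formed after values had been seen, and some repeat genes of fixed lists. The comparisons also share arrays. Members of a family can share sequence or regulation, which random lists lack.

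The calculation was tested on simulated arrays with known changes, with scatter taken from the genotype differences at matched signal. A first criterion, that 80% of all 8-fold changes be recovered in both directions, failed: among all changed probe sets 96.8% of 8-fold increases but 62.5% of 8-fold decreases were recovered in the wild-type light comparison, since the floor hides decreases of dim probe sets. The criterion was then limited to probe sets bright before the change, of which 100% and 95.8% were recovered. At 2-fold, the threshold of the calls, 54.7% of increases and 42.2% of decreases of such bright probe sets were recovered. In the untreated genotype comparison 66.0% and 31.5% were. Without any change, 27.3% of probe sets past the filter and 11.8% of bright ones were 2-fold apart in the wild-type light comparison. The scatter holds any true genotype difference, so these last shares do not measure error. Of 1600 lists without change, 75 (4.69%) fell outside the percentile limits; genes varied independently in these simulations.

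Each count was repeated with quantile normalisation, equal medians, floors at the 10th and 50th percentiles, a pseudocount of 16 in place of the floor, no brightness filter, bright probe sets only, without probe sets whose names mark shared sequence, and a 3-fold threshold, all planned. Counts without plastid-encoded probe sets were added after seeing the data. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.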

Results

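Transcript levels were measured on Affymetrix arrays in Arabidopsis thaliana plants of 2 genotypes, the Col-0 wild type and erf6-1, a mutant of the ethylene response transcription factor gene ERF6. Plants of each genotype were sampled untreated and after 2 h under light of 2000 µmol m-2 s-1. Each of the 4 groups had 1 array, so no difference below could be set against variation between replicates, and the values describe these 4 arrays only. The series was designed to find genes regulated by ERF6 under oxidative stress and high light. ERF6 itself was not analysed here.

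The table held MAS5 signals for 22746 probe sets. The 2% trimmed mean of the signal lay between 493 and 495 in all 4 arrays. The median signal was 279 in the untreated wild type, 321 in untreated erf6-1, 208 in the high-light wild type and 207 in high-light erf6-1. Signals above the floor of 100 were found for 71.0%, 72.6%, 68.5% and 67.8% of probe sets in the same order. Across bright probe sets, Spearman's correlation was 0.912 between both high-light arrays and 0.763 between both untreated arrays. Across all probe sets these values were 0.834 and 0.623. Genes are not independent replicates, so these values carry no test.

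The first comparison asked how wild-type plants responded to high light. Genes of heat, cold and oxidative stress stood at the top. HSP22.0 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, was 63.6-fold higher in the high-light array, with a signal of 15766 against 248. COR15A (AT2G42540), a cold-regulated protein of the chloroplast stroma, was at least 82.3-fold higher, and its neighbour COR15B (AT2G42530) at least 32.5-fold higher. COR47, a dehydrin, was 11.1-fold higher, and ALDH7B4, an aldehyde dehydrogenase, had a signal of 14659 against 1461.

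Among the lists fixed in advance, 5 of 7 measured heat shock factors and chaperones were at least 2-fold higher in the high-light array of the wild type and none was 2-fold lower. Their median log2 difference of 1.70 lay at percentile 99.98 of random lists of matched signal. Small heat shock proteins led this list, with AT1G52560 (HSP26.5) at a log2 difference of 4.01 and AT5G37670 (HSP15.7) at 1.99, whereas the cochaperone HOP3 stood at 0.02. Of 10 oxidative stress marker genes, 7 were at least 2-fold higher and 1, CML37, was 2-fold lower; the median was 1.71, above all 10000 random lists. This list held AT1G05340 at a log2 difference of 4.33, AT1G19020 at 3.09, the zinc finger repressor STZ (ZAT10) at 2.31 and the mitochondrial stress marker UPOX at 2.28. All 4 measured abscisic acid, cold and drought genes were at least 2-fold higher, with a median of 4.25; the dehydrin LTI30 was 7.93-fold higher. Phenylpropanoid and flavonoid genes had a median of 0.79 at percentile 98.13, with 2 of 6 members 2-fold higher, the flavonoid glucosyltransferase UGT78D2 at 1.89 and DFR, a reductase of anthocyanin synthesis; with each array's median signal set to the same value, that percentile was 97.04 and no longer past the limit. Antioxidant enzymes did not stand apart, with a median of -0.48 at percentile 9.46, although glutathione reductase GR1 was at 1.74.

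Photosynthesis genes lay on the lower side in the wild type. The photosystem II subunit PSBW was 5.93-fold lower in the high-light array, with a signal of 10835 against 64266, and the photosystem I subunit PSAE-1 had a log2 difference of -1.18. All 7 measured photosystem, electron transport and Calvin cycle genes had negative values, with a median of -0.67 at percentile 1.25; after quantile normalisation the median was -0.52 and the percentile 9.25, no longer past the limit, and with equal medians -0.24 and 1.09. Plastid-encoded transcripts had a median of -1.36 over 68 genes, below all random lists, and 46 of them were at least 2-fold lower. The photosystem II genes psbI, psbK and psbM were 10.5-fold, 9.93-fold and 9.39-fold lower. Among single genes, expansin EXPA8, which loosens cell walls, was at -3.01, the cell expansion gene EXO, chosen after its values had been seen, at -2.42, and BCAT4, an enzyme of glucosinolate synthesis, at -1.93. Both measured auxin early response genes were lower, with IAA29 at -2.22, a bound, and WES1 (GH3.5), which conjugates auxin to amino acids, at -1.95. The largest differences on the lower side among genes above the floor on both arrays were AT3G28550, 23.7-fold lower, and AT1G14330, with a log2 difference of -4.17.

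In total, 2455 probe sets were at least 2-fold higher and 4103 at least 2-fold lower in the high-light array of the wild type, out of 17173 past the brightness filter. This balance depended on scaling and on signal. Higher values made up 37.4% of the 2-fold differences as deposited, 50.6% after quantile normalisation, 60.7% with equal medians, and 62.7% among the 4964 bright probe sets, where 695 were higher and 414 lower.

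The second comparison asked how erf6-1 responded to high light. AT1G05340, an oxidative stress marker, was 51.4-fold higher in the high-light array of erf6-1, and the U-box ubiquitin ligase PUB19 was 48.1-fold higher, with a signal of 4892 against 102. HSP22.0 was 34.1-fold higher, COR15A at least 92.8-fold, COR15B 19.4-fold and COR47 15.3-fold. The largest bound was that of AT3G02480, at least 291-fold higher, with a signal of 29064. ATG8H, a ubiquitin-like protein of autophagosomes, was 20.6-fold higher.

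Heat shock factors and chaperones were at least 2-fold higher in 6 of 7 cases in erf6-1, with a median of 1.61 at percentile 99.92. Oxidative stress markers had a median of 1.83, above all random lists, with 7 of 10 members 2-fold higher and 1, AT1G57630, 2-fold lower. The 4 abscisic acid, cold and drought genes were all at least 2-fold higher, with a median of 4.11. Phenylpropanoid and flavonoid genes had a median of -0.12 at percentile 61.88, which was 0.28 after quantile normalisation and 0.34 with equal medians, within the limits each time. For photosystem, electron transport and Calvin cycle genes the median was -0.26 at percentile 6.88, and with equal medians it was 0.37. PSBW stood at -1.36 and PSAE-1 at -0.06. Plastid-encoded genes had a median of -0.66, below all random lists, with 23 of 68 at least 2-fold lower; with equal medians it was -0.04, still below all random lists. On the lower side, AT1G47400 was 29.5-fold lower, EXPA8 7.92-fold and EXO 4.86-fold lower. In the high-light array of erf6-1, 2873 probe sets were at least 2-fold higher and 5122 at least 2-fold lower. Higher values made up 35.9% of the 2-fold differences as deposited, 50.6% after quantile normalisation, 63.9% with equal medians and 69.7% among bright probe sets.

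Both responses were alike where the signal was bright. Of the 695 bright probe sets at least 2-fold higher in the wild type, 423 were also 2-fold higher in erf6-1, where 120.7 would be shared if the calls were independent, and 3 were 2-fold lower. Of the 414 on the lower side 163 were shared, where 31.3 would be, and 4 were 2-fold higher. Pearson's correlation of the log2 differences was 0.690 across bright probe sets, with a slope of 0.714 for erf6-1 on wild type, and 0.317 across all probe sets past the filter.

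**Figure D1:**
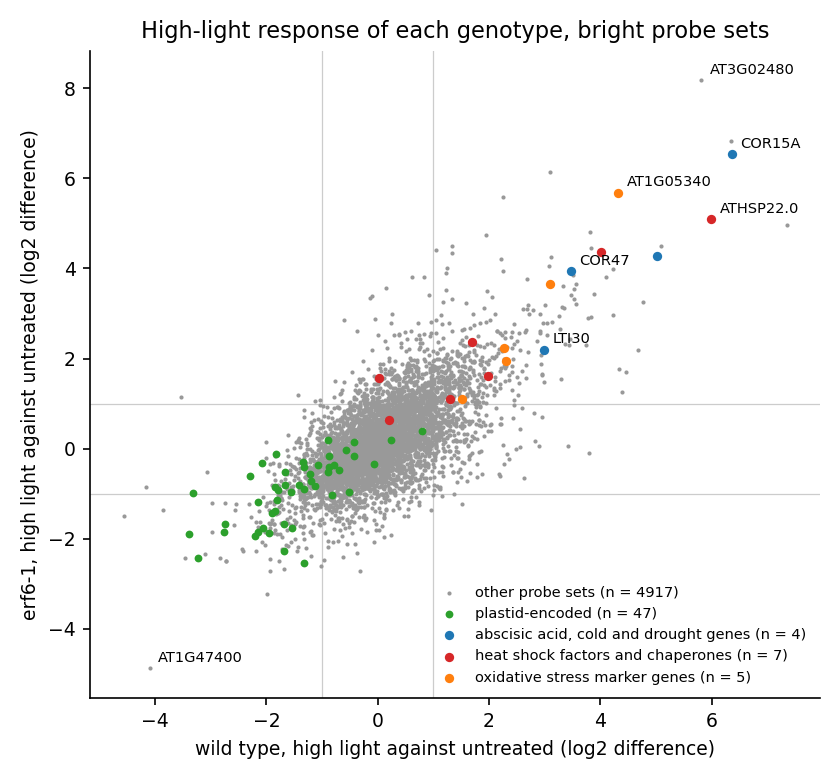
Log2 difference between the high-light and the untreated array in the wild type (horizontal axis) and in erf6-1 (vertical axis), 1 point per bright probe set and 1 array per group; grey lines mark 2-fold. The 4 abscisic acid, cold and drought genes and all 7 heat shock factors and chaperones lie above 0 on both axes, most plastid-encoded probe sets below 0, and Pearson's correlation over all bright probe sets is 0.690; values at the floor are bounds.

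The third comparison asked how erf6-1 differed from the wild type without treatment. The nuclear gene furthest on the lower side was AT3G28550, whose signal was 449 in erf6-1 and 7038 in the wild type, a log2 difference of -3.97. PUB19 was 9.03-fold lower, with a signal of 102 against 920, and AER, an alkenal reductase, was 9.12-fold lower. Plastid-encoded genes were low as a group, with a median log2 difference of -0.96 over 68 genes, below all random lists; 33 were at least 2-fold lower and 3, rpoA, psbD and rps14, at least 2-fold higher. Above the floor on both arrays, the largest differences among them were petN, 13.1-fold lower, ndhD, 10.8-fold lower, and matK, 9.78-fold lower, whereas rpoA, a subunit of the plastid RNA polymerase, had a log2 difference of 1.86. On the higher side, the leading genes all had signals near the floor in the wild type, such as AT2G20690, with 1133 against 120, and AT3G27590, with 900 against 103. None of the 6 fixed lists with a percentile stood apart from random lists in this comparison. Reference genes, used to compare samples in expression assays, had a median of -0.87 at percentile 7.26, with 2 of 5, PEX4 (UBC21) and AT5G15710, at least 2-fold lower. After high light these genes had medians of -0.13 in the wild type and 0.74 in erf6-1, at percentiles 50.81 and 92.29. At least 2-fold higher were 1 of 5 in the wild type and 2 of 5 in erf6-1, and none was 2-fold lower. AT2G28390 (SAND), near the floor when untreated, was at 1.62 and 1.96, and PEX4 at -0.13 and 1.11. Tubulins, a family examined after its values had been seen, had a median of -0.69 at percentile 2.48, which was 2.57 with equal medians and 2.6 with the pseudocount, no longer past the limit, and 0.94 after quantile normalisation.

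Between the untreated arrays, 4075 probe sets were at least 2-fold higher and 3369 at least 2-fold lower in erf6-1, or 43.4% of those past the filter. Few of these were bright. With all probe sets ranked by mean signal and split into 5 classes of equal size, 2-fold differences covered 10.1% of the dimmest class, where the floor hides them, 64.2% of the next and 11.7% of the brightest, and among bright probe sets 258 were higher and 384 lower. The balance depended on scaling here too, with higher values at 54.7% of the 2-fold differences as deposited, 49.4% after quantile normalisation and 45.4% with equal medians.

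**Figure D2:**
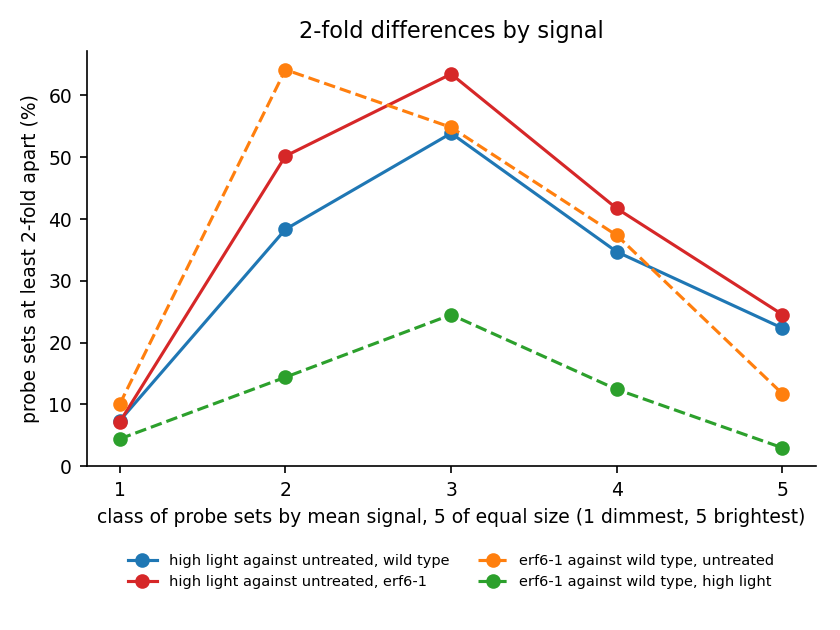
Share of probe sets at least 2-fold apart (vertical axis, %) in each of 5 equal classes of all probe sets ranked by mean signal (horizontal axis, from dimmest to brightest), for the 4 comparisons of array pairs. In the brightest class the untreated genotype comparison reaches 11.7% and the high-light genotype comparison 2.97%.

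The fourth comparison asked how erf6-1 differed from the wild type after high light. Several single genes on the lower side have roles in defence. They were put together after their values had been seen. Most genes of the fixed defence lists had no named probe set, so too few were left for a percentile. AT4G33720, a protein of the pathogenesis-related family 1, had a signal of 5924 in the high-light wild type and 80.3 in high-light erf6-1, at least 59.2-fold lower. The defensins PDF1.2 (AT5G44420), an ethylene and jasmonate marker, and PDF1.2b (AT2G26020) were at least 15.4-fold and 7.12-fold lower; the PDF1.2b probe set can also bind related sequences. AT4G16260, a beta-1,3-glucanase, was 7.41-fold lower, with 553 against 4100, and the peroxidase AT5G19890 5.70-fold lower. OSM34, an osmotin chosen after its values had been seen, was 2.42-fold lower, with 2910 against 7040.

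In the wild type these genes were higher in the high-light array than in the untreated one, by log2 differences of 3.90 for AT4G33720, at least 3.94 for PDF1.2 and 2.52 for OSM34; PDF1.2b had a signal of 2698 against 169. In erf6-1 the log2 differences were -2.27 for AT4G33720, a bound, -0.59 for PDF1.2b and 1.18 for OSM34, and PDF1.2 was under the floor on both arrays. Both measured members of the fixed list of defensins and ethylene-jasmonate defence genes were therefore on the lower side of the genotype comparison. Beside these, root markers had log2 differences of 0.20 for PYK10, -1.05 for EXPA7 and -1.99 for EXPA18 in the same pair of arrays. The only measured gene of the salicylic acid list, WRKY53, went the other way, with signals of 292.5 in high-light erf6-1 and 99.7 in the high-light wild type, a log2 difference of at least 1.55.

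**Figure D3:**
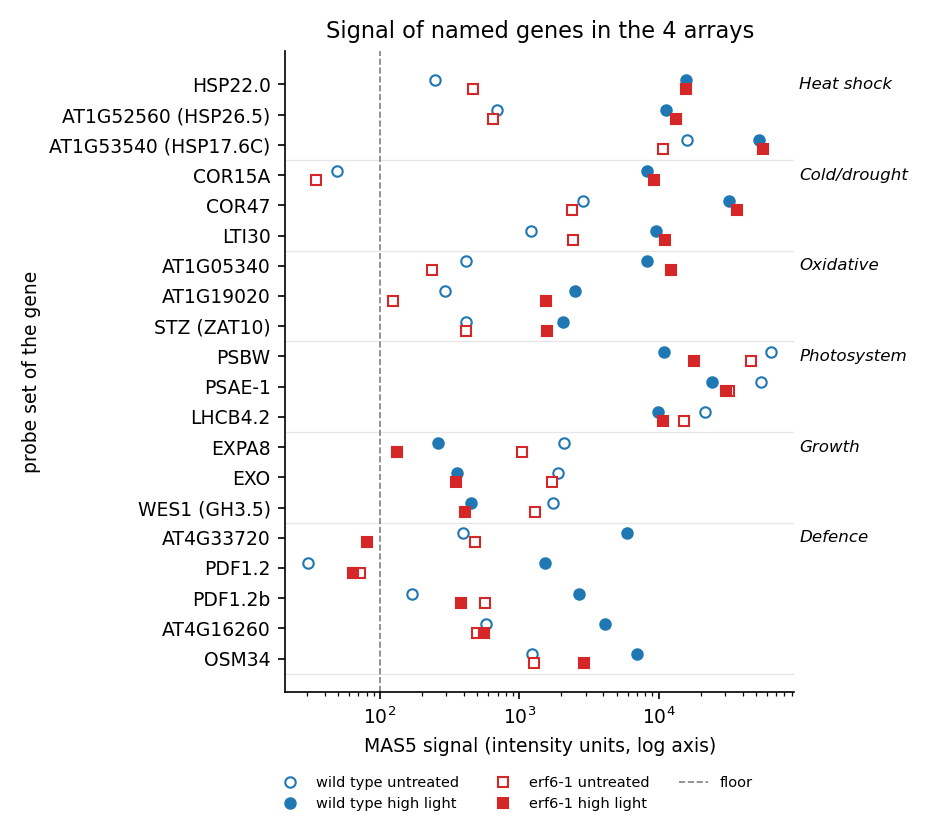
MAS5 signal (horizontal log axis, intensity units) of named genes in the wild type (circles) and erf6-1 (squares), untreated (open) and after high light (filled), 1 array each; the dashed line is the floor of 100. Heat shock and cold genes have similar signals in both high-light arrays, while the defence genes, put together after their values had been seen, are high in the wild-type high-light array, with AT4G33720 at 5924 against 80.3 in erf6-1.

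Plastid-encoded genes also differed between the genotypes after high light. ndhD, of the plastid NADH dehydrogenase-like complex, was 8.68-fold lower in erf6-1, psbA, the photosystem II reaction centre protein D1, 5.76-fold lower, and the ATP synthase gene atpF 4.39-fold lower. rpoA was 4.38-fold higher. The median of all 68 was -0.32, below all random lists, with 21 at least 2-fold lower and 6 at least 2-fold higher. Their genotype differences were alike in the untreated and the high-light arrays, with Pearson's correlation 0.758 across these probe sets. Over all probe sets past the filter that correlation was 0.035, and over bright probe sets without the plastid ones 0.155.

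**Figure D4:**
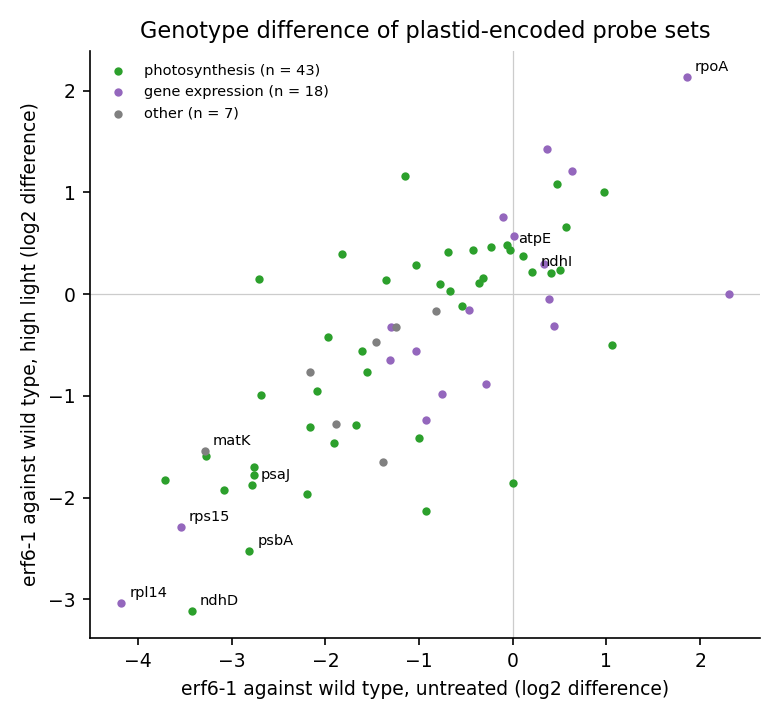
Log2 difference of erf6-1 from the wild type without treatment (horizontal axis) and after high light (vertical axis) for the 68 plastid-encoded probe sets past the filter, 1 point each. Genes such as ndhD, psbA and rpl14 are low and rpoA is high on both axes, and Pearson's correlation is 0.758.

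Heat shock and cold genes had similar signals in both high-light arrays. HSP22.0 had signals of 15733 and 15766, and the 7 heat shock factors and chaperones had log2 differences of at most 0.38, with a median of 0.21. The 4 abscisic acid, cold and drought genes lay between 0.05 and 0.21. The 10 oxidative stress markers had a median of -0.20 at percentile 6.76, within the limits, but were past them with equal medians, at -0.32 and percentile 2.16, and with the pseudocount, at -0.46 and percentile 1.41; their values ranged from -0.88, a bound, to 0.56. STZ, the only measured gene of the list of candidate ERF6 targets, was at -0.37. On the higher side, AT2G25510 was 4.39-fold higher in erf6-1, with a signal of 14238 against 3241, and AT1G14330 3.94-fold higher. In all, 1135 probe sets were at least 2-fold higher and 1201 at least 2-fold lower in high-light erf6-1, 13.6% of those past the filter, and 72 and 88 among bright ones.

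The last comparison asked which genes responded to high light differently in the 2 genotypes, as the response of erf6-1 minus that of the wild type. PDF1.2b was at -4.59 and AT4G16260 at -2.66, whereas WRKY53 was at 3.16, a bound, and defensins and defensin-like proteins, a family formed after values had been seen, had a median of -0.22 at percentile 39.37, within the limits. AER, whose signal was low in untreated erf6-1 alone, was at 3.46. Among genes above the floor on all 4 arrays, AT1G71020 was lowest at -4.86 and AT5G52070 highest at 4.14, and neither was bright. Plastid-encoded genes had a median of 0.61, above all random lists. Their light response in the wild type and their untreated genotype difference use the same untreated wild-type array, so these are not separate observations. Plastid probe sets held 8.14% of the signal in that array and 4.39% in untreated erf6-1. After high light they held 2.24% in the wild type and 1.93% in erf6-1. No fixed list with a percentile stood apart. In total 3721 probe sets were at least 2-fold higher and 4397 at least 2-fold lower by this measure, and 476 and 342 among bright ones; higher values made up 45.8% as deposited, 50.3% after quantile normalisation and 54.2% with equal medians, and a value here adds the errors of 4 arrays.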

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

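The tests on noise and scaling of the untreated arrays were written down before their results were seen; every other test in this part, and the check of mean signals that overturned the planned reading of the noise test, was chosen only after the result it concerns was seen.

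Of 295 genes screened by the rule for named genes or among the extremes of bright genes, 32 were at least 2-fold higher in the high-light array of 1 genotype and at least 2-fold lower in that of the other. These differences were not tested, since each group had 1 array, and 4 were bright. Among all 17173 probe sets past the filter 692 went opposite ways in this manner, and 7 of the 4964 bright ones did. Many of the screened genes were picked for extreme differences in these same arrays. Their share is therefore no measure of how common such genes are. The values that follow are the log2 response of erf6-1 minus that of the wild type, and are bounds where an array was at the floor. In 17 genes the response was higher in the wild type: AT4G33720 (-6.17), AT1G71020 (-4.86), AT2G20690 (-4.77), AT5G57655 (-4.43), AT1G02870 (-4.11), AT3G12030 (-3.91), TRM82 (-3.87), AT4G16460 (-3.81), AT1G77480 (-3.77), AT4G16790 (-3.52), AT1G78720 (-3.46), DPE1 (-3.37), AT5G62720 (-3.31), AT5G19890 (-3.16), AT1G75510 (-2.75), AT1G04040 (-2.38) and AT3G56130 (-2.21). In 15 genes it was higher in erf6-1: AT5G23610 (2.19), WRKY53 (3.16), NANA (3.35), AT1G52200 (3.42), AT5G10690 (3.44), AT5G19900 (3.47), AT1G17620 (3.53), AT1G54680 (3.57), AT3G23450 (3.57), AT2G18890 (3.61), AT1G61667 (4.04), AT5G52070 (4.14), AT1G71970 (4.16), AT1G07310 (4.94) and AT5G11910 (5.18). The bright ones were AT1G75510, AT1G04040, AT3G56130 and AT5G23610, which were chosen after their values had been seen.

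The first pattern was the large number of 2-fold differences between the untreated arrays, 7444 probe sets. Scaling alone is argued against, since 7093 were counted after quantile normalisation, 95.3% of that number. In these arrays, a genotype difference present in both light conditions is argued against as the main source for probe sets that were not bright. After high light, 50.5% (binomial limits 48.8% and 52.2%) of the 3544 nuclear or unnamed ones above the floor on both arrays lay on the same side. It stays open for the bright ones, of which 60.3% of 620 did (56.3% and 64.2%). These limits treat probe sets as independent, which they are not, and do not measure the spread between plants. Bright probe sets also shared 25 lower and 9 higher calls where independence would give 6.8 and 3.7, in a count that included plastid-encoded ones. Measurement noise stays open: over 63 genes with 2 probe sets the difference correlated at -0.060 (bootstrap limits -0.318 and 0.187), which by the plan would have counted as noise, but even the mean signals of such probe sets correlated at only 0.262, so that test decides nothing. A genotype difference confined to untreated plants, or a difference between single plant samples, may also contribute and was not tested.

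The second pattern was the genotype difference of plastid transcripts, alike in both light conditions. Array noise is argued against, since the correlation of 0.758 over 68 plastid genes exceeded all 10000 random lists of nuclear genes of matched signal, which reached 0.546. One shift of all plastid RNA is argued against as the whole account: 17 plastid probe sets lay at least 2-fold from the plastid median on the same side in both light conditions and 0 on opposite sides. A difference between the plants or RNA preparations of both genotypes cannot be told apart from an effect of the erf6-1 mutation, since there was 1 array per group.

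The third pattern was the low signal of 6 defence genes in high-light erf6-1, with a median log2 difference of -2.86, chosen for showing it. Less root tissue in that sample stays open, since the 3 measured root markers had a median of -1.05 but ranged from -1.99 to 0.20. A lowering shared by other defence genes stays open as well, since 8 others, WRKY53 of the fixed lists and 7 of the defensin family formed after values had been seen, had a median of -0.14 at percentile 10.1 (bootstrap limits -1.04 and 0.91) and went both ways. Between the untreated arrays the 6 genes had a median of 0.17, as would be seen if the wild-type high-light sample alone were unusual, or if the mutation acted on these genes only under high light. These accounts cannot be told apart with 1 array per group.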

How the results depend on the processing

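Results without plastid-encoded probe sets were added after seeing the data. All other settings were chosen before the data were examined. The list percentiles counted below include those of families formed after values had been seen. No count moved by more than 1.5 times under quantile normalisation, without the filter, without shared-sequence probe sets or without plastid-encoded ones. Correlations were repeated only with quantile normalisation, the pseudocount, bright probe sets and without plastid-encoded ones, and none changed sign. The side with more 2-fold differences turned in several cases, as the counts show. Counts are given as higher and lower, for the light comparison in the wild type, then in erf6-1, the genotype comparison untreated, then under high light, and the difference of responses. Quantile normalisation gave 3158 and 3080, 3699 and 3608, 3502 and 3591, 1339 and 1415, and 3947 and 3895. A 3-fold threshold gave 1068 and 1936, 1434 and 3025, 2465 and 1882, 261 and 270, and 2099 and 2723, fewer by construction. Bright probe sets gave 695 and 414, 862 and 375, 258 and 384, 72 and 88, and 476 and 342, fewer by construction; the correlation of responses became 0.690 and that of genotype differences 0.189, and the cause was not tested. The floor at the 50th percentile gave 1196 and 1742, 1485 and 2523, 1942 and 1432, 226 and 230, and 1710 and 2172, since a higher floor shrinks differences. Under high light the genotype comparison gave 2093 and 2236 with the floor at the 10th percentile and 1955 and 2091 with the pseudocount, as a lower floor widens them. Equal medians gave 4007 and 2591 in the wild type and 5098 and 2881 in erf6-1. The median log2 difference of probe sets past the filter moved from -0.13 to 0.17 and from -0.22 to 0.33. Past the filter were 16779 probe sets with equal medians and 17173 as deposited. Between the untreated arrays equal medians gave 3068 and 3697, that median moving from 0.01 to -0.12. For the difference of responses they gave 4160 and 3510, with the median moving from -0.02 to 0.19. Of the list percentiles, 3 passed inside the limits and 3 outside with equal medians, 4 and 2 with quantile normalisation, and 3 and 2 with the pseudocount, and the cause was not tested. Named genes moved by more than the scatter between probe sets of a gene in 7 cases with the pseudocount and 1 with quantile normalisation. That scatter, 0.638 to 1.32 log2, includes probe sets reading different parts of a gene. The mean signals of such probe sets correlated at only 0.262. Few moves past so wide a limit therefore do not show that the values were stable. The signal of ERF6 was not analysed here, so none of the settings chosen for it gave a value. No paired analysis was possible because each group had 1 array and the sample titles give no pairing. An additive fit of genotype and light, with 1 residual degree of freedom, was not made. Signal over background limits decreases of dim probe sets, which the floor hides.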

Other observations

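The families in this part, and the members named from them, were chosen after values of single genes had been seen, and no hypothesis is tested here.

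Late embryogenesis abundant and cold-regulated proteins, which accumulate in drying or chilled tissue, were at least 2-fold higher after high light in all 6 measured cases in each genotype, with medians of 3.29 in the wild type and 4.26 in erf6-1, above all random lists. COR15A, COR15B, COR47 and LTI30 are among them. These are the measured abscisic acid, cold and drought genes given above, so the family is not a separate observation. LEA4-5 was at 3.11 and 4.25, and LEA18 at 1.76 in the wild type, with signals of 1964 against 84.4 in erf6-1. Autophagy proteins had medians of 0.69 at percentile 97.98 and 0.94 at percentile 99.30; after quantile normalisation the first of these percentiles was 97.04. ATG8H was at 4.18, a bound, in the wild type and at 4.36 in erf6-1, ATG8B 1.07 and 1.38, and ATG8G, on the other side, -0.54 and -0.55. UDP-glycosyltransferases had a median of 0.36 at percentile 99.77 in the wild type, with 13 of 37 at least 2-fold higher and 3 lower. In erf6-1 12 were higher and 7 lower, with a median of 0.00 at percentile 91.09. That is the value given to genes under the floor on both arrays. With the pseudocount the erf6-1 median was 0.26 at percentile 99.02, past the limit. UGT87A2 was at 2.00 and 1.98. U-box ligases had a median of -1.57 at percentile 1.2 in erf6-1 and of -0.01 in the wild type, but PUB19 was at 5.59 and 2.26.

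Between the high-light arrays, expansins had a median of -0.43 in erf6-1 against the wild type, at percentile 0.83, with 3 of 15, EXLA2, EXPA18 and EXPA7, at least 2-fold lower; it was -0.63 after quantile normalisation, -0.68 with equal medians and -0.83 with the pseudocount. EXPA18 and EXPA7 are also 2 of the 3 measured root markers, so less root tissue in that sample stays open here too. Defensins and defensin-like proteins had a median of -0.47 at percentile 0.65, which was -1.17 at 0.02 after quantile normalisation, -1.29 below all random lists with equal medians, and at 5.44 with the pseudocount. The family includes PDF1.2 and PDF1.2b, put together with the defence genes above for their low signal in high-light erf6-1. Of the 9 measured members, 4 were at least 2-fold lower and 0 at least 2-fold higher. Without PDF1.2 and PDF1.2b, the other members together with WRKY53 had a median of -0.14 at percentile 10.08, within the limits. WRKY53 is not of this family and was higher, at a bound of 1.55. The other members were not examined without it, so whether the family result rests on PDF1.2 and PDF1.2b is not known. In the wild type the light response of the whole family had a median of 0.68 at percentile 99.28, and 96.91 with equal medians and 97.27 with the pseudocount. LSM RNA-binding proteins responded lower in erf6-1 than in the wild type, with a median difference of -1.24 at percentile 1.07. Nuclear photosystem and antenna genes, which include PSBW and other genes of the fixed lists, had a median of -0.59 at percentile 2.03 in the wild type. After quantile normalisation that percentile was 12.75. Their difference of responses was 0.65 at percentile 98.26, and at 90.59 after quantile normalisation. Between the high-light arrays their percentile was past the limit only after quantile normalisation, at 97.65. Beta-glucosidases lay within the limits in the wild type, with a median of -0.94 at percentile 3.42, and outside with equal medians at 0.85 and after quantile normalisation at 1.49. Plastid photosynthesis genes had medians of -1.41 in the wild type and -0.55 in erf6-1 over 43 probe sets, and plastid genes of transcription and translation of -1.17 and -0.77 over 18. With equal medians, the directions of the families above apart from random lists were kept.

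The remaining fixed lists had 1 to 3 measured members. Of 2 antenna genes, LHCB4.2 was at -1.12 in the wild type and -0.51 in erf6-1, and LHCB4.1 at -0.38 and 0.30. Of 2 photoprotection genes, HYH was at 0.31 and 0.18, and LHCB4.3 at -0.39 and -0.13. The glutathione S-transferase GSTU25 was at 1.90 and 1.72, and GSTU20 at -0.52 and -0.78. The clock gene GI was at 0.62 and 1.87. Among unfolded protein response genes, CRT1b was at -0.41 and -1.26, BZIP60 at 0.20 and 0.89, and ATERDJ3B at -0.28 and -0.58. The glucosinolate gene UGT74B1 was at 0.08 and 1.21, beside BCAT4 at -1.93 and -1.76. Sugar starvation genes were at 0.56 and -0.06 for AKINBETA1, 0.33 and -1.29 for MCCA, and -0.41 and -0.73 for IVD. No gene of the lists of ethylene response factors, senescence, flower and seed genes had a named probe set, so their signals were not examined. The only named gene of the jasmonate list, THI2.1, was under the filter.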
